A study of Mus musculus with 2 samples.

How the data were processed

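Gene expression was measured in single cells of 2 primary cultures of mouse ventricular wall, 1 library per culture, after 2 days of differentiation. Per the labels, newborn ventricular walls were dissociated and grown to confluence, other cells were shaken off overnight, and serum-free medium started differentiation. Cells were then dissociated with trypsin and labelled with a cell surface protein strategy, and libraries were made with the 10x Genomics 3′ v3 kit. The labels call the samples duplicates and do not say whether the cultures differed in litter, day or sequencing run.

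The authors' deposited counts are UMI counts per gene and cell, made with Cell Ranger (versions 3 and 5.0.1) on mm10, per the submitters' processing notes. Which version made which library is not given in the sources used here. The deposited cell metadata names the library, 1 of 14 populations (unannotated cells among them) and 1 of 5 cell cycle classes for each cell. How these names were assigned, and how doublets were treated, is not given in the sources used here. All values in the count table were whole numbers. The lowest cell had 2523 UMIs in replicate 1 and 2502 in replicate 2, and the highest mitochondrial share was 9.00% and 9.99%, so cells had been filtered before deposit. No further cell was removed. Both libraries' reads carry molecular identifiers, and intervals and floors cover counting error only. A count of 0 over a whole library allows 3 counts, which is 0.0173 CPM in replicate 1 and 0.0425 CPM in replicate 2. Of the gene identifiers in the files, 32235 (99.8%) were found in GENCODE M21, which gave the mm10 coordinates. The axoneme list members Dnai1 and Dnai2 were matched to the older symbols Dnaic1 and Dnaic2.

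Counts were summed per library and population, which gave 26 sums over the 13 populations with at least 20 cells in each library. Fibroblasts, with 18 cells in replicate 1, were left out of the fit. edgeR 4.0.16 (R 4.3.3) was used with TMM factors (0.739 to 1.20), its default low count filter, which left 15877 genes, and robust quasi-likelihood tests with 12 residual degrees of freedom. The model held population and library. Each comparison averaged the populations of a side equally, all populations shared 1 estimate of the spread, and tests were two-sided with Benjamini-Hochberg adjustment at 0.05. The multiciliated lineage is the 5 stages from early deuterosomal cells to MCCs, and non-cycling progenitors are progenitors I and II. In the 3 comparisons 714, 691 and 592 genes had 0 UMIs in a population that was averaged, so their values depend on the small count the fit adds. Of these 201, 199 and 93 passed the test, and 199, 197 and 225 had an adjusted p of 1. The standard error is the log2 fold change divided by the root of its F statistic. The library was a block because populations of 1 library share a culture, a substrain and a run. The deviations of the populations from their means correlated within a library with a median of 0.184 and a lowest value of −0.00168.

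The comparisons, 23 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The 14 comparisons between single populations, the alternative without unannotated cells and the G2 and M list without Tubb4b were chosen afterwards. Of the lists, 19 had at least 5 members past the filter and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation. Named genes are the 8 largest changes each way among genes past the test with a mean log2 CPM of at least 5 and the same direction in both libraries. Predicted genes, mitochondrial genes and ribosomal protein genes were left out of these. Named genes also include, from each list, up to 2 members with the highest and 2 with the lowest changes past the test, the cyclins, Cdk1, Cdk2, Plk1, Plk4, Fbxo5, Fbxo43, Cdc20, Cdc20b, Gmnc, Mcidas, Foxj1 and Deup1. Ccnb3 was below the low count filter. For the libraries they are the 5 largest ratios each way among genes with at least 100 UMIs.

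Levels are CPM of the summed counts, given as the mean and SD of the 2 libraries, and list levels are mean CPM over all list members. For shares of cells with a UMI, each cell was thinned to 5000 UMIs, and 607 shallower cells were left out. Shares of cells carry exact Clopper-Pearson 95% intervals (scipy 1.17.1), and library levels exact Poisson intervals. The libraries differed by far more than sampling noise, with a chi-square of 190.0 per gene over 18305 genes with at least 20 UMIs.

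The fit was tested on simulated counts with 1 mean per gene over all populations, the sizes and spread of the real data and 200 changed genes, 50 per fold. At folds of 1.25, 1.5, 2 and 4 it recovered 16%, 62%, 58% and 82% of changed genes for the lineage against cycling progenitors (15349 genes tested). It recovered 36%, 70%, 80% and 98% against non-cycling progenitors (15306 genes) and 16%, 60%, 76% and 96% for the deuterosomal stages (15339 genes). It called 5, 6 and 5 unchanged genes in the same order. Unlike the real counts, the simulated ones held no other difference between populations or libraries, so these values may not carry over to the real data.

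Alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no low count filter, no replicate block, the populations of the 2 sides alone and 34 cells drawn per population and library. Further ones were cells thinned to 5000 UMIs, leaving out the deepest 5% of cells, leaving out either replicate, and leaving out unannotated cells. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the rest.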

Results

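Primary cultures from the lateral ventricular walls of newborn mice hold progenitors of ependymal cells, the multiciliated cells that line the brain ventricles. The cultures were profiled by droplet single-cell RNA sequencing 2 days after serum was withdrawn to start differentiation. The design has 1 group of 2 samples, with replicate 1 from C57BL/6N mice and replicate 2 from C57BL/6J mice, and no other condition. The deposited table holds 16401 cells. Replicate 1 gave 12028 cells and 173510950 unique molecular identifiers (UMIs), with a median of 12708 UMIs and 4134 genes per cell. Replicate 2 gave 4373 cells and 70611931 UMIs, with a median of 14409 UMIs and 4406 genes per cell. Because the labels name no treatment, the comparisons are between cell populations inside the same 2 libraries, using the population names in the submitters' cell metadata. These names presumably rest on the same expression values, so markers that define a population, such as Deup1 or Mki67, check its name and are not separate evidence.

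The 5 stages of the multiciliated lineage made up 39.0% of cells in replicate 1 (95% exact interval 38.1 to 39.8) and 30.7% in replicate 2 (29.4 to 32.1). These stages are early, mid and late deuterosomal cells, early multiciliated cells (MCCs) and MCCs. The first 3 are named after deuterosomes, the structures on which most centrioles form before they become the base of each cilium. Mid deuterosomal cells held 7.69% ± 0.535 of cells (SD, n = 2 libraries). MCCs held 17.0% in replicate 1 (16.4 to 17.7) and 6.04% in replicate 2 (5.35 to 6.78), a 2.82-fold difference that counting error does not cover. Early deuterosomal cells differed the other way, at 5.51% and 10.3%. Non-cycling progenitors, named progenitors I and II in the metadata, held 34.4% and 44.9%, and cycling progenitors 4.32% and 5.47%. Neuroblasts, oligodendrocyte precursor cells (OPCs), oligodendrocytes, microglia and fibroblasts held 4.32% and 5.95% together. Cells without a population name held 18.0% and 12.9%. The flask was shaken to remove other cells and the cells were dissociated with trypsin, and both steps can set these shares.

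Each cell also carries a deposited cell cycle class (G0, G1, S, S/G2 or G2/M), and these classes followed the stages of the lineage. Cells of class S, S/G2 or G2/M made up 97.1% ± 0.888 of mid deuterosomal cells and 94.3% ± 0.990 of late deuterosomal cells (SD, n = 2 libraries). They made up 24.4% ± 3.55 of early deuterosomal cells, 5.86% ± 2.71 of early MCCs and 65.4% ± 1.92 of cycling progenitors. No MCC carried such a class (0 of 2047 and 0 of 264 cells, which allows up to 0.180% and 1.39%). Within mid deuterosomal cells the class S/G2 alone held 80.7% ± 2.81. The classes presumably come from transcripts, though the sources used here do not say so, and they do not by themselves show cells in cycle.

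**Figure D1:**
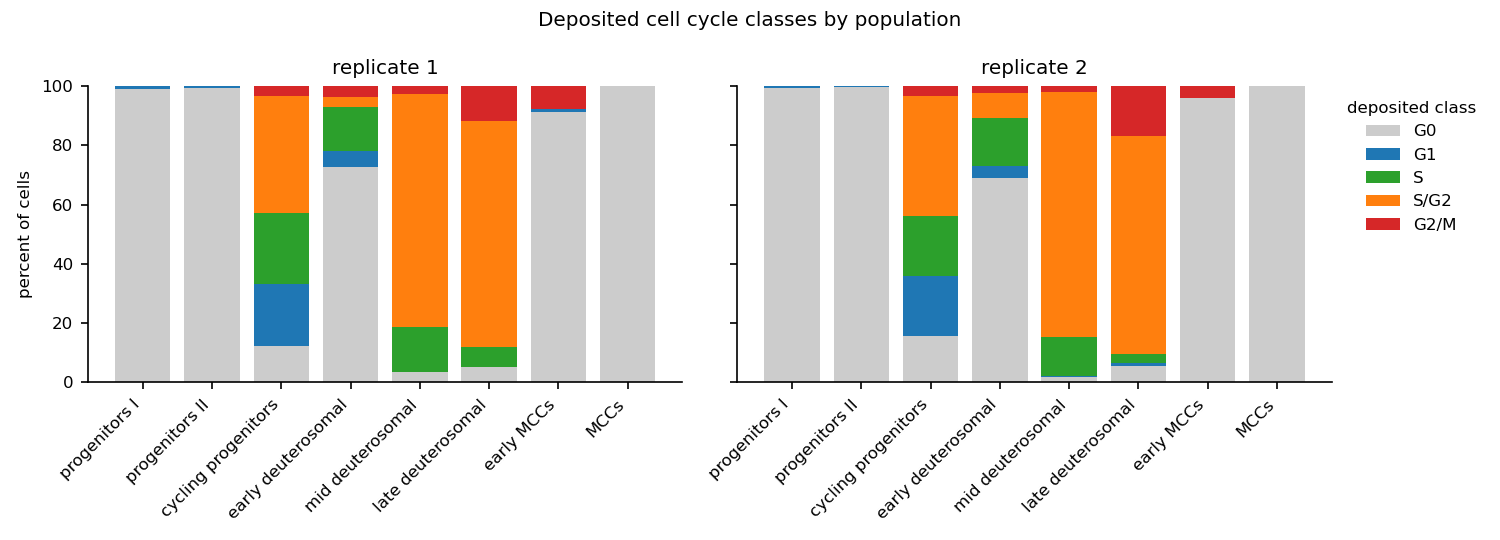
Share of cells in percent (vertical axis) with each deposited cell cycle class (G0, G1, S, S/G2, G2/M; stacked colours) in 8 populations (horizontal axis), with 1 panel per replicate. Classes S, S/G2 and G2/M together hold 97.1% of mid deuterosomal cells and 65.4% of cycling progenitors on average over the 2 libraries, and 0 MCCs.

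The series title places an endocycle, a cell cycle without division, in multiciliated differentiation, so the lineage was first set against dividing progenitors of the same cultures. Mki67, a marker of proliferating cells, was 75.5-fold lower in the lineage than in cycling progenitors (log2 fold change −6.24 ± 0.25 (SE, n = 2 libraries), adjusted p = 9.93e-11). Ccna2, the A-type cyclin of dividing cells, was 43.9-fold lower (−5.46 ± 0.13, adjusted p = 1.4e-19). Its relative Ccna1, known mainly from male meiosis, was 3.48-fold higher (1.80 ± 0.21, adjusted p = 2.87e-06). Fbxo5, an inhibitor of the anaphase-promoting complex (APC/C), was 49.4-fold lower (−5.63 ± 0.19, adjusted p = 4.26e-15). Its paralog Fbxo43 had 0.262 CPM (UMIs scaled to one library total) in cycling progenitors and 24.4 CPM ± 4.31 (SD, n = 2 libraries) in mid deuterosomal cells.

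Cyclins split in this comparison. Of 13 cyclins tested, 2 were higher in the lineage, Ccna1 and Ccno (2.35 ± 0.32), a cyclin-like gene needed for multiciliation. The other 11 were lower, among them the D-type Ccnd1 (−4.53 ± 0.31), the E-type Ccne1 (−3.74 ± 0.18) and Ccne2 (−6.20 ± 0.18), and the B-type Ccnb1 (−2.56 ± 0.10) and Ccnb2 (−3.28 ± 0.11). Taken from 1 library at a time (log2 CPM with 2 counts added), Ccnd1 was at −4.25 in replicate 1 and −5.13 in replicate 2. The remaining declines were Ccnf −4.66, Ccnd2 −2.33, Ccng2 −1.15, Ccnd3 −1.05 and Ccng1 −0.68. The cyclin list was lower as a set (camera adjusted p = 1.31e-06, and adjusted p = 0.0116 with an estimated correlation). Of 20 cyclin-dependent kinases (CDKs) and their regulators, 16 were lower, including Cdk1 (−2.10 ± 0.11), Cdk2 (−2.48 ± 0.15) and Plk1 (−3.07 ± 0.10). The exception that was higher was Cdk5 (0.76 ± 0.10), a kinase known from neurons (set adjusted p = 8.33e-08, and 0.0101 as the adjusted p with an estimated correlation). With 34 cells drawn per population and library Cdk5 no longer passed the test.

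All 43 S phase genes were lower in the lineage, and 37 of 40 genes of DNA replication licensing and firing were lower, with Cdc6 at −6.96 ± 0.31 and Mcm5 at −5.85 ± 0.15. Cycling progenitors were presumably named from such transcripts, so the direction of the cell cycle lists here partly follows from the choice of reference. Orc3 was the 1 licensing gene that was higher (0.78 ± 0.12). Of 54 G2 and M phase genes, 52 were lower, and the 2 that were higher were Tubb4b (2.84-fold), a tubulin of cilia, and Ckap5 (0.58 ± 0.19), a microtubule polymerase. All 41 kinetochore and cytokinesis genes were lower, from Birc5 (−4.87 ± 0.14) and Aurkb (−4.37 ± 0.11) to Bub3 (−0.43 ± 0.08). These 4 lists kept their set calls with an estimated correlation (adjusted p = 0.0352 for each). Among E2F, Rb and DREAM factors 16 of 21 were lower, with E2f2 at −5.84 ± 0.41 and Foxm1 at −3.82 ± 0.16, and Myb (2.82 ± 0.25) and E2f4 (0.35 ± 0.10) were higher (set adjusted p = 1.17e-06, and adjusted p = 0.0516 with an estimated correlation). APC/C genes moved both ways, with 6 higher, such as Cdc20b (3.68 ± 0.34), and 9 of 21 lower, such as Cdc20 (−2.08 ± 0.11), and the set did not pass (adjusted p = 0.306). In replicate 1 and replicate 2 alone Cdc20b was at 2.94 and 5.40, Cdc6 at −5.70 and −5.48 and E2f2 at −4.46 and −3.67. Early MCCs held 0 UMIs of Cdc6 and late deuterosomal cells 0 of E2f2, so both values depend on the count that the fit adds. Cdc20b and E2f4 no longer passed with 34 cells per population and library, nor did E2f4 in cells thinned to 5000 UMIs.

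The genes of cilia and centrioles went the other way. All 40 axoneme genes were higher, including Spag17 (4.30 ± 0.34) of the central apparatus and Ccdc153 (4.36 ± 0.59), as were 25 of 26 intraflagellar transport genes, such as Ift172 (2.31 ± 0.12). The largest other increases were Dmkn (4.42 ± 0.31), Hdc (4.41 ± 0.40), which makes histamine, Ccdc192 (4.27 ± 0.27), Meig1 (4.25 ± 0.63), Cfap57 (4.21 ± 0.24) and the dynein assembly factor Dnaaf1 (4.14 ± 0.23). Of 25 centriole amplification genes 17 were higher, led by Ccdc78 (4.63 ± 0.38). Another 5 were lower, including Plk4 (−0.73 ± 0.15), the kinase that starts centriole formation, and Sass6 (−0.87 ± 0.09) of the cartwheel. These values average the 5 stages equally. In thinned cells of replicates 1 and 2, Plk4 was found in 29.7% and 35.2% of cycling progenitors. It was found in more early (47.9% and 50.6%) and mid deuterosomal cells (74.97% and 76.3%). It was found in fewer late deuterosomal cells (22.2% and 19.3%), early MCCs (4.32% and 6%) and MCCs (3.78% and 6.13%). These shares were not tested. Of 13 multiciliation regulators 10 were higher, among them Trp73 (3.28 ± 0.22), Mcidas (2.53 ± 0.33) and Foxj1 (2.23 ± 0.39). Gmnc, which acts at the top of the pathway, did not pass (0.21 ± 0.15, adjusted p = 0.245). Plk4 and Mcidas no longer passed, and Gmnc changed direction, with 34 cells per population and library. In replicate 1 and replicate 2 alone the values were 3.79 and 5.32 for Ccdc153, 4.08 and 5.04 for Dmkn, 4.02 and 4.97 for Ccdc192 and 3.63 and 4.95 for Meig1. They were 3.74 and 5.11 for Cfap57, 3.59 and 5.64 for Dnaaf1, 4.68 and 3.45 for Ccdc78 and 2.09 and 3.92 for Mcidas. With an estimated correlation the set calls were lost, at adjusted p = 0.218 for axoneme and for intraflagellar transport, 0.176 for centriole genes and 0.223 for regulators. Their preset-correlation values were 3.12e-12, 1.64e-09, 0.000236 and 0.0191 in that order.

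In all, 4864 genes were higher and 4548 lower of 15877 tested. Other decreases were Hmmr (−5.50), Pclaf (−5.38), Cdca3 (−5.24), Pbk (−4.36) and Ube2c (−4.28), all genes of dividing cells. Markers of other cells moved too. Of 23 radial glia and astroglia genes 15 were lower, including Id3 (−3.47 ± 0.20), as were 9 of 15 neuronal genes (set adjusted p = 0.00265 and 0.0247, and adjusted p = 0.421 and 0.218 with an estimated correlation). Radial glia genes that were higher were Hopx (1.21 ± 0.26), which no longer passed with 34 cells per population and library, and Slc1a2 (0.81 ± 0.14). Of 6 mural cell and fibroblast genes 5 were lower, including Pdgfrb (4.01-fold), though the set did not pass (adjusted p = 0.0704). Of 11 oligodendrocyte genes 4 were lower, including Olig2 (−4.02 ± 0.33, with −3.47 in replicate 1 and −5.02 in replicate 2 alone), and Cnp was higher (2.78-fold) (set adjusted p = 0.215), and the microglia list had 0 of 11 past the test. Adjusted over the list alone, every list of this comparison kept its counts of higher and lower genes. The adjusted p-values rest on the spread left after the model takes out population means and the shift between these 2 libraries. That spread is pooled over all fitted populations, and it does not measure the full spread between cultures.

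Against non-cycling progenitors, which asks what differentiation adds to resting cells, the lineage had more transcripts of both cilia and mitosis. Cdk1 was 4.54-fold higher (2.18 ± 0.11 (SE, n = 2 libraries), adjusted p = 1.08e-13) and Ccnb1 was higher as well (3.81 ± 0.15, adjusted p = 1.13e-16). Plk1, a mitotic kinase, was 27.2-fold higher (4.77 ± 0.21), and Cdc20, the mitotic activator of the APC/C, 17.3-fold higher (4.12 ± 0.15). Ccne1 (0.11 ± 0.24, adjusted p = 0.706), Ccne2 (−0.42 ± 0.33, adjusted p = 0.263) and Cdk2 (−0.08 ± 0.14, adjusted p = 0.619) did not pass the test. Ccne1 and Ccne2 changed direction with 34 cells per population and library, as did Ccne1 without the deepest cells. These values average the 5 stages equally, and levels by stage are given further on.

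Of 54 G2 and M phase genes 48 were higher than in non-cycling progenitors, with Ckap2l at 5.23 ± 0.34 and Cdc25c at 4.99 ± 0.38, and 2 were lower, Psrc1 (−2.64 ± 0.13) and Cbx5 (−0.42 ± 0.06). Of 41 kinetochore and cytokinesis genes 36 were higher, such as Knl1 (3.56 ± 0.34). In replicate 1 and replicate 2 alone Cdc25c was at 3.76 and 3.36. Both set calls, at adjusted p = 2.04e-10 and 6.53e-09, were lost at adjusted p = 0.360 with an estimated correlation. S phase genes were mixed, with 21 higher, such as Rad51ap1 (3.24 ± 0.24) and E2f8 (2.62 ± 0.31), 11 lower, such as Ung (−1.42 ± 0.28), and 11 not past the test (set adjusted p = 0.467). Replication licensing and firing had 20 higher, led by the kinase subunit Dbf4 (2.00 ± 0.13), and 12 of 40 lower, including Mcm5 (−1.35 ± 0.21) and Mcm2 (−1.04 ± 0.14) of the replicative helicase (set adjusted p = 0.345). E2f8, Ung and Mcm5 no longer passed with 34 cells per population and library.

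Cyclins had 5 higher, 5 lower and 3 of 13 not past the test (set adjusted p = 0.903). Ccnb2 (4.23 ± 0.21), Ccna1 (3.68 ± 0.17), Ccna2 (2.53 ± 0.27) and Ccno (1.95 ± 0.20) were higher beside Ccnb1. Ccnd1 (−2.97 ± 0.28), Ccnd2 (−2.08 ± 0.11), Ccnd3 (−1.10 ± 0.06), Ccng1 (−0.86 ± 0.07) and Ccng2 (−1.02 ± 0.10) were lower, and Ccnf was at 1.37 ± 0.66 (adjusted p = 0.0645). Of the CDK list 7 were higher and 9 of 20 lower, including the inhibitor Cdkn1c (−1.88 ± 0.23) and Cdk6 (−1.15 ± 0.06) (set adjusted p = 0.900). The APC/C list had 15 of 21 higher, such as Cdc20b (5.03 ± 0.27), and 2 lower (set adjusted p = 0.000226, and adjusted p = 0.360 with an estimated correlation). Fbxo5 was at 0.43 ± 0.38 (adjusted p = 0.328). E2F, Rb and DREAM factors had 11 of 21 higher and 5 lower, including E2f3 (−1.39 ± 0.11) (set adjusted p = 0.544). Cdc20b and E2f3 no longer passed with 34 cells per population and library. Ccnf passed with the DESeq2 Wald test and with only the 2 sides in the fit, and Fbxo5 passed in thinned cells.

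All 25 centriole amplification genes and all 40 axoneme genes were higher than in non-cycling progenitors, with Ccdc78 at 4.40 ± 0.23 (4.27 in replicate 1 and 3.73 in replicate 2 alone), Plk4 at 2.70 ± 0.15, Tmem212 at 5.61 ± 0.49 and Spag17 at 5.47 ± 0.24. Intraflagellar transport had 25 of 26 higher, such as Traf3ip1 (2.07 ± 0.08). Their set adjusted p-values were 7.04e-11, 2.04e-10 and 6.47e-08, and with an estimated correlation the adjusted p was 0.161 for centriole genes and 0.360 for the others. Regulators had 9 of 13 higher, among them Trp73 (4.00 ± 0.14), Mcidas (3.98 ± 0.29) and Foxj1 (1.67 ± 0.27), and 2 lower, Gmnc (−0.85 ± 0.09) and E2f5 (−0.70 ± 0.07) (set adjusted p = 0.0412, and adjusted p = 0.360 with an estimated correlation). Mcidas and Gmnc no longer passed with 34 cells per population and library. Foxn4, a regulator of motile cilia genes, had 0.0995 CPM in progenitors I, 0 in progenitors II and 38.3 CPM ± 3.88 in mid deuterosomal cells. The other large increases were Ccdc192 (5.62 ± 0.19), Nme9 (5.56 ± 0.28), the glutamate transporter Slc17a8 (5.34 ± 0.17), Ccdc153 (5.32 ± 0.44) and Crip3 (5.11 ± 0.27).

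Glial genes were lower in the lineage than in non-cycling progenitors. Of 23 radial glia and astroglia genes 20 were lower and 0 higher, led by Id3 (−4.05 ± 0.17) and Id1 (−2.65 ± 0.12), inhibitors of differentiation (set adjusted p = 8.34e-05, and adjusted p = 0.360 with an estimated correlation). Notch pathway genes had 9 of 17 lower, including the target Hes5 (−2.61 ± 0.34), and 3 higher, including the ligand Jag2 (3.61 ± 0.26) (set adjusted p = 0.128). Hes5 rests on replicate 2, since it was at −0.97 in replicate 1 alone, which had 47 UMIs of it in all cells, and at −2.58 in replicate 2 alone, and it did not pass without the replicate block (adjusted p = 0.103). Jag2 was at 3.01 and 3.14. Of 6 mural cell and fibroblast genes 3 were lower, including Pdgfrb (−2.85 ± 0.10), and of 11 oligodendrocyte genes 2 were lower, Olig1 and Olig2, and 2 higher, Cnp and Enpp6. Of 15 neuronal genes 4 were lower and Dlx2 was higher, and of 11 microglia genes Laptm5 was higher. None of these sets passed (adjusted p = 0.197, 0.544, 0.528 and 0.815), and with 34 cells per population and library Olig2, Enpp6 and Laptm5 no longer passed and Dlx2 changed direction, and Laptm5 did not pass in thinned cells. Other large decreases were Igfbp5 (−3.62 ± 0.32), Elobl (−3.29 ± 0.26), Olig1 (−3.06 ± 0.21), Olfm2 (−2.93 ± 0.09), Meg3 (−2.84 ± 0.25) and Fmod (−2.78 ± 0.14). Of 12 genes that respond to dissociation 10 were also lower, such as Dusp1 (−1.74 ± 0.12) (set adjusted p = 0.0349, and adjusted p = 0.360 with an estimated correlation). In all, 5713 genes were higher and 5535 lower of 15877. Adjusted over the list alone, 49 G2 and M genes were higher and 21 radial glia and astroglia genes lower, and the other lists kept their counts.

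Within the lineage, the deuterosomal stages were compared with early MCCs and MCCs to ask which genes go with centriole amplification. The mitotic gene Hmmr was 95.2-fold higher in the deuterosomal stages (6.57 ± 0.38 (SE, n = 2 libraries), adjusted p = 2.64e-10), and Mcidas, a regulator of multiciliation, 79.3-fold higher (6.31 ± 0.20, adjusted p = 8.46e-18). Aurka, a kinase of centrosomes and mitosis, was 68.6-fold higher (6.10 ± 0.20). Plk4 was 17.3-fold higher (4.11 ± 0.16), Ccno 17.6-fold (4.13 ± 0.23), Cdk1 17.8-fold (4.16 ± 0.13) and Ccnb1 21.7-fold (4.44 ± 0.14). Ccno was at 4.42 in replicate 1 and 3.44 in replicate 2 alone. Mcidas, Plk4 and Ccno are markers of the centriole amplification stage. If the stage names rest on such transcripts, their differences check the names and are not separate evidence. Ccna1 (0.19 ± 0.15, adjusted p = 0.290) and Foxj1 (0.36 ± 0.27, adjusted p = 0.291) did not pass the test. Both passed in thinned cells, and Foxj1 also with only the 2 sides in the fit.

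Of 41 kinetochore and cytokinesis genes 40 were higher in the deuterosomal stages, with Knl1 at 5.77 ± 0.23 and Cdca8 at 5.57 ± 0.32, and Nuf2 alone was lower (−0.57 ± 0.18), which did not pass without the replicate block (adjusted p = 0.138). Of 54 G2 and M phase genes 48 were higher, as were 22 of 25 centriole amplification genes, led by Stil (5.26 ± 0.20). The lower centriole gene was Cetn4 (−1.25 ± 0.15). S phase genes had 31 of 43 higher, such as Rad51ap1 (4.67 ± 0.19) and Clspn (3.83 ± 0.23), and 9 lower. Licensing and firing had 30 of 40 higher, such as Cdt1 (3.69 ± 0.22, with 3.70 in replicate 1 and 3.02 in replicate 2 alone) and Dbf4 (3.68 ± 0.14), and 7 lower, such as Mcm6 (−0.98 ± 0.12). The set adjusted p-values were 1.84e-24 for the kinetochore and the G2 and M lists, 1.51e-12 for centriole genes, 3.72e-05 for S phase and 4.2e-05 for licensing. None held with an estimated correlation, at adjusted p = 0.0973 for the first 3, 0.402 for S phase and 0.367 for licensing.

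Cyclins had 8 of 13 higher, including Ccnf (4.45 ± 0.40), Ccnb2 (2.99 ± 0.17), Ccne1 (2.61 ± 0.32), Ccna2 (1.90 ± 0.25), Ccne2 (1.55 ± 0.52) and Ccnd2 (0.42 ± 0.15). Ccng1 was lower (−0.51 ± 0.09), and Ccnd1 (0.74 ± 0.50, adjusted p = 0.231), Ccnd3 (0.05 ± 0.08, adjusted p = 0.612) and Ccng2 (−0.19 ± 0.14, adjusted p = 0.280) did not pass. CDKs had 13 of 20 higher, including Plk1 (4.39 ± 0.15) and Cdk2 (1.00 ± 0.19). APC/C genes had 16 of 21 higher, led by Cdc20 (5.12 ± 0.14) and Cdc20b (4.24 ± 0.16), and E2F, Rb and DREAM factors 14 of 21, led by E2f7 (4.08 ± 0.16) and E2f8 (2.67 ± 0.29). In replicate 1 and replicate 2 alone Ccne2 was at 1.54 and 0.41, Ccnf at 3.39 and 3.68, Cdc20b at 4.19 and 3.61 and E2f8 at 2.30 and 3.40. Ccnd1 was at 0.66 and 1.45 in the same order. The set adjusted p-values of these 4 lists were 0.00479, 3.72e-05, 6.46e-06 and 0.00066, and with an estimated correlation the adjusted p was 0.101, 0.0973, 0.0973 and 0.198. Multiciliation regulators had 7 of 13 higher and 3 lower, including Gmnc (−0.67 ± 0.12) and Rfx3 (−0.54 ± 0.13) (set adjusted p = 0.0244, and adjusted p = 0.367 with an estimated correlation). Without the replicate block Rfx3 (adjusted p = 0.0688) and Ccnd2 (adjusted p = 0.0538) did not pass, nor did Ccnd2 without the deepest cells or without the low count filter. Ccna2, Ccne1, Ccne2, Ccnf and Cdk2 no longer passed with 34 cells per population and library, nor did Ccnd2 and Cdk2 in thinned cells, while Ccnd1 passed with only the 2 sides in the fit.

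Axoneme genes had 0 of 40 higher and 27 lower in the deuterosomal stages, with Tmem212 at −3.06 ± 0.32 and Dnah1 at −0.48 ± 0.10 (set adjusted p = 0.000375, and adjusted p = 0.667 with an estimated correlation). Summed over the list, the early stage was low, with medians of 5758 and 4862 CPM per cell in replicates 1 and 2. Mid deuterosomal cells, at 17330 and 15424 CPM, were already near MCCs, at 16360 and 15598 CPM. This sum weights abundant genes most. Sntn, of the ciliary tip, had 0.650 CPM ± 0.370 in mid deuterosomal cells and 17.5 CPM ± 2.04 in MCCs (SD, n = 2 libraries). Intraflagellar transport had 5 higher, such as Ttc21b (1.63 ± 0.12), and 8 of 26 lower (set adjusted p = 0.977). The other large increases were Cenpe (5.28 ± 0.24), Ckap2l (4.97 ± 0.29), Plvap (4.77 ± 0.19, with 4.85 in replicate 1 and 4.10 in replicate 2 alone) and Hyls1 (4.75 ± 0.18), which acts at centrioles. The other decreases were Fam166b (−2.52 ± 0.12), Nnat (−2.51 ± 0.27), Ccn2 (−2.40 ± 0.31), Crip1 (−2.36 ± 0.16), the clock gene Dbp (−2.32 ± 0.11), Sostdc1 (−2.30 ± 0.19) and Tctex1d4 (−2.25 ± 0.22). Of 12 dissociation genes 11 were lower, such as Nr4a1 (−1.71 ± 0.23, though adjusted p = 0.156 without the replicate block) (set adjusted p = 0.000545, and adjusted p = 0.187 with an estimated correlation). Radial glia and astroglia genes had 9 of 23 lower and Notch2 higher, of 11 oligodendrocyte genes Olig1 (1.82 ± 0.35), Olig2 and Mbp were higher, and of 15 neuronal genes 4 were higher, such as Dlx2 (1.23 ± 0.15), and 2 lower. Of 6 mural cell and fibroblast genes Pdgfrb was lower, and none of these 4 sets passed (adjusted p = 0.117, 0.326, 0.373 and 0.695). With 34 cells per population and library Notch2, Olig2, Dlx2 and Pdgfrb no longer passed and Mbp changed direction. Mbp also did not pass in thinned cells or without unannotated cells, nor Notch2 without the replicate block (adjusted p = 0.151).

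In this comparison 4239 genes were higher and 4551 lower of 15877. With DESeq2 size factors in place of the TMM factors the split was 3214 and 6001, with the median log2 fold change of all genes moving from −0.03 to −0.17, and with the DESeq2 Wald test it was 3183 and 5749. Among the named genes Ccnd3 alone changed direction with these factors (−0.08), and 4 no longer passed the test, including Ccnd2. Adjusted over the list alone, 32 S phase genes and 15 E2F, Rb and DREAM factors were higher, 4 intraflagellar transport and 2 oligodendrocyte genes were higher, and 12 dissociation genes, 2 G2 and M genes and 1 neuronal gene were lower. The other lists named for this comparison kept their counts.

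Levels by stage showed where in the lineage cell cycle genes peaked. Ccna1 rose from 49.3 CPM ± 6.84 in early deuterosomal cells to 365 CPM ± 69.9 in mid and 614 CPM ± 34.5 in late deuterosomal cells, and was at 405 CPM ± 13.6 in early MCCs and 99.8 CPM ± 27.7 in MCCs (SD, n = 2 libraries). Ccna2 had 198 CPM ± 21.3 in cycling progenitors and 8.73 CPM ± 0.831 in mid deuterosomal cells. Ccnb1 had 195 CPM ± 16.6 in mid deuterosomal cells, 301 CPM ± 8.03 in late deuterosomal cells and 199 CPM ± 24.8 in cycling progenitors. Cdk1 had 645 CPM ± 6.22 in mid deuterosomal cells and 656 CPM ± 26.0 in cycling progenitors. By edgeR, mid deuterosomal cells did not differ past the test from cycling progenitors in Ccnb1 (0.09 ± 0.13, adjusted p = 0.581) or Cdk1 (0.09 ± 0.16, adjusted p = 0.654). They differed in Ccna1 (2.65 ± 0.24, adjusted p = 1.9e-07), Ccna2 (−4.38 ± 0.18, adjusted p = 9.75e-15) and Mki67 (−4.23 ± 0.36, adjusted p = 2.5e-07). Cycling progenitors are a mixed reference, with 13.8% of cells in class G0 and 20.8% in class G1 on average. Those of class S/G2 or G2/M had 983 and 965 CPM of Cdk1 in replicates 1 and 2. Mid deuterosomal cells had 641 and 649 CPM, a difference that was not tested.

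Other regulators peaked at other stages. Mcidas had 107 CPM ± 11.3 in early and 134 CPM ± 1.26 in mid deuterosomal cells, and 16.1 CPM ± 3.12 in late ones. Ccno followed the same order, with 270 CPM ± 68.0, 342 CPM ± 39.8 and 45.6 CPM ± 10.7. Plk4 had 189 CPM ± 34.8, 336 CPM ± 13.8 and 57.8 CPM ± 12.4. Gmnc had 44.0 CPM ± 4.85 in progenitors II and 7.03 CPM ± 2.62 in mid deuterosomal cells. Fbxo5 stayed between 2.61 and 4.67 CPM in the deuterosomal stages, against 83.9 CPM ± 6.32 in cycling progenitors. Ccno, Mcidas and Cdc20b lie close together on the plus strand of chromosome 13 (mm10, GENCODE M21), at 112987802 to 112990777, 112993845 to 113000394 and 113035111 to 113091195. Ccna1 and Ccna2 both lie on the minus strand of chromosome 3, at 55045469 to 55055501 and 36564865 to 36572150.

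**Figure D2:**
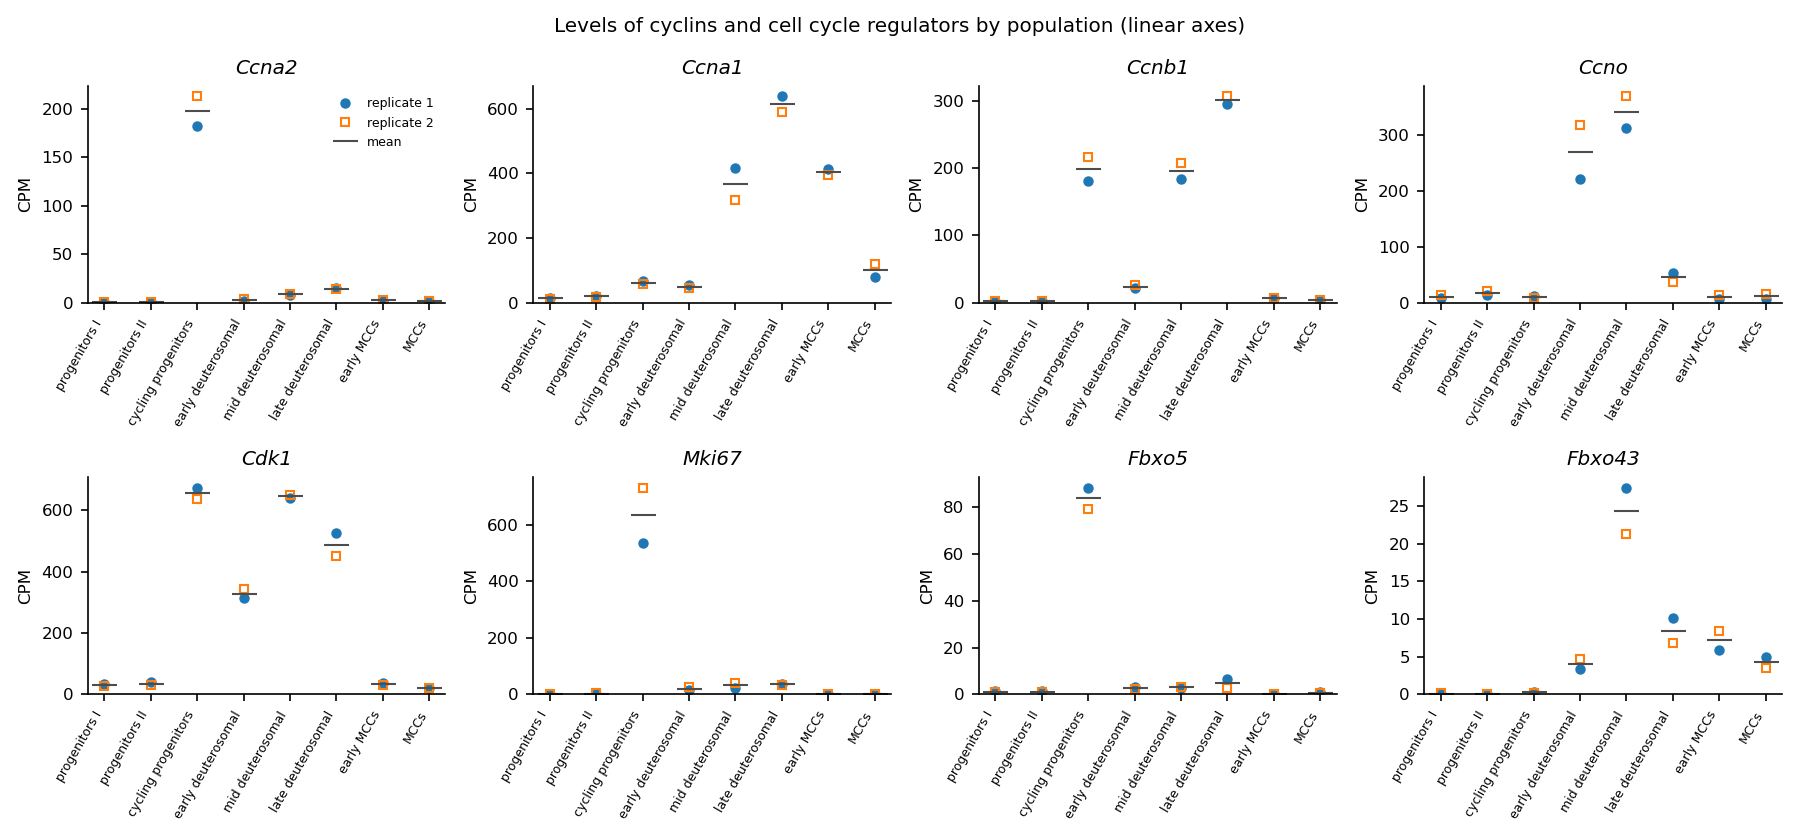
CPM (vertical axes, linear from 0) of Ccna2, Ccna1, Ccnb1, Ccno, Cdk1, Mki67, Fbxo5 and Fbxo43 in 8 populations (horizontal axis), with replicate 1 as filled circles, replicate 2 as open squares and their mean as a dash. Ccna2, Mki67 and Fbxo5 are highest in cycling progenitors, Ccno and Fbxo43 in mid deuterosomal cells, and Ccna1 and Ccnb1 in late deuterosomal cells.

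As lists, replication genes and mitotic genes had different profiles. The mean CPM of S phase genes was 28.0% ± 0.425 of that in cycling progenitors in early deuterosomal cells, 19.9% ± 0.649 in mid and 17.6% ± 1.68 in late deuterosomal cells, and 13.4% in progenitors I (SD, n = 2 libraries). G2 and M phase genes without the cilium tubulin Tubb4b were at 28.0% ± 2.08 in early, 59.7% ± 0.317 in mid and 54.2% ± 5.17 in late deuterosomal cells, and at 12.0% in MCCs. With Tubb4b the mid deuterosomal value was 82.9% ± 2.15. Kinetochore and cytokinesis genes were at 18.6%, 47.6% and 43.9% in the same stages and at 7.14% in MCCs. These means weight abundant genes most, and the cycling progenitors they are set against include cells of class G0 or G1. As shares of thinned cells with a UMI, the S phase values of the early and mid stages were higher. The mid value of G2 and M phase genes without Tubb4b was higher too, as given further on.

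Mid deuterosomal cells had 46 of 54 G2 and M phase genes and 38 of 41 kinetochore genes higher than early ones, and 20 of 43 S phase genes lower. Pcna, the replication clamp, fell with them (−2.33 ± 0.27, adjusted p = 6.76e-06), a gene chosen after its values were seen. Against cycling progenitors the mid stage still had 38 of 54 G2 and M phase genes lower and 9 higher. Early MCCs had 47 of 54 G2 and M phase genes and 40 of 41 kinetochore genes lower than late deuterosomal cells (set adjusted p = 0.0156 for both with an estimated correlation). Cdc20 fell with them (−5.59 ± 0.20, adjusted p = 9.75e-15), and Ccna1 did not pass (−0.60 ± 0.22, adjusted p = 0.063).

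**Figure D3:**
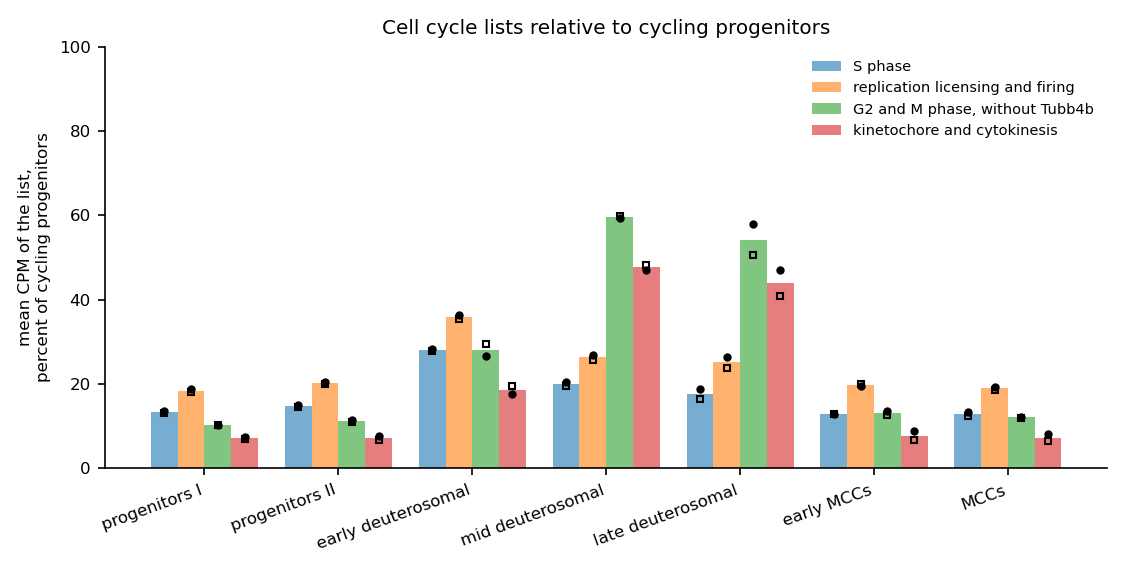
Mean CPM of 4 cell cycle gene lists (S phase, replication licensing and firing, G2 and M phase without Tubb4b, kinetochore and cytokinesis) as a percent of their level in cycling progenitors (vertical axis, 0 to 100), by population (horizontal axis). Bars are means of the 2 libraries, filled circles are replicate 1 and open squares replicate 2. S phase genes are at 28.0% in early and 19.9% in mid deuterosomal cells, and G2 and M phase genes at 28.0% and 59.7%.

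In single cells thinned to 5000 UMIs, Deup1 and Cdk1 were found together in 91.1% of mid deuterosomal cells of replicate 1 (95% exact interval 89.0 to 92.9) and 93.6% of replicate 2 (90.5 to 96.0). In oligodendrocytes, which should lack both, Cdk1 was found in 1.59% of 63 cells and 5.71% of 35 cells, and both genes together in 0. Cdk1 was more common in other cells mostly of class G0. In replicates 1 and 2 it was found in 15.2% and 11.1% of progenitors I, 18.7% and 14.1% of progenitors II and 10.3% and 7.66% of MCCs. Both genes together were found in 1.102% and 0.578% of progenitors I, 4.04% and 1.087% of progenitors II and 2.43% and 0.766% of MCCs. Median depths before thinning were 17984 and 20436 UMIs in mid deuterosomal cells and 8994.5 and 10979.5 in oligodendrocytes. Ccna1 was found in 78.7% and 74.6% of mid deuterosomal cells, against 24.1% and 23.2% of cycling progenitors, 6.70% and 4.87% of progenitors I and 0 of 63 and 0 of 35 oligodendrocytes. Ccna2 was found in 3.43% (2.32 to 4.86) and 3.47% (1.80 to 5.98), against 44.6% and 48.9% of cycling progenitors and 0.220% and 0.495% of progenitors I. Oligodendrocytes, with 2 of 63 and 0 of 35 cells, are too few to set a background for Ccna2.

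The 2 libraries were also compared as they stand, with 1 library per substrain and no replicate behind either value. Among 15484 genes with at least 100 UMIs, 540 were at least 2-fold higher in replicate 1 and 275 in replicate 2. Within progenitors I, the largest named population, the counts were 141 and 154 of 11959 genes. Xist, the RNA that silences the inactive X chromosome of female cells, had 0.271 CPM in replicate 1 (exact Poisson 95% interval 0.199 to 0.360) and 269.1 CPM in replicate 2 (265.3 to 273.0). Thinned cells with Xist and no UMIs of 4 Y-linked genes made up 0.0606% of replicate 1 and 34.5% of replicate 2. Those with Y-linked UMIs alone made up 47.6% and 32.8%. The libraries thus differed in the sex of their cells as well as in substrain. Hes5 had 0.271 CPM from 47 UMIs and 14.9 CPM from 1054 UMIs, a 55.1-fold difference. Gm17167 had 0.0519 and 8.03 CPM, and Ccrl2 and Vtn were 12.1-fold and 10.9-fold higher in replicate 2. By population, Ccrl2 was higher in replicate 2 in 10 of 13 and Vtn in only 6 of 13. Within progenitors I Vtn had 0.215 and 0.952 CPM. In the other direction Gm42031 was 14.3-fold, Clec4d 12.5-fold and the chemokine Ccl5 11.8-fold higher in replicate 1. F630028O10Rik and Gm36529 rest on 3 UMIs each in replicate 2, with 0.726 CPM (0.605 to 0.865) and 0.617 CPM (0.505 to 0.745) in replicate 1 against 0.0425 CPM (0.00876 to 0.124).

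Nnt, which carries a deletion in C57BL/6J, had 3.26 CPM in replicate 1 and 3.50 CPM in replicate 2, with overlapping intervals (2.99 to 3.54 and 3.08 to 3.96). Whether 3′ tags reach the deleted part was not checked, so Nnt does not check the labels. The gene annotation also holds another entry named Nnt, whose values are not given here. Wdfy1 had 75.9 and 68.6 CPM. Ide had 32.6 and 65.1 CPM and was higher in replicate 2 in 13 of 13 populations. Entpd4 and its near-identical copy Entpd4b had 0 UMIs, and reads shared by such copies may not be counted, so they are uncertain. Of 12 genes that respond to dissociation 10 were higher in replicate 2, with Fos at 209.8 and 1019 CPM, Egr1 at 141.7 and 427 CPM and Dusp1 at 62.0 and 202 CPM, while Hspa1a (18.9 and 11.5 CPM) and Hspa1b (6.28 and 3.50 CPM) were lower in it. Xist aside, none of these differences can be assigned to substrain, to sex or to any other difference between the 2 cultures.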

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

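All tests in this part were chosen after the results were seen. Transcripts of motile cilia appeared in cells on neither side of the comparisons, though these cells entered the shared fit. Among unannotated cells, 85.5% in replicate 1 and 78.9% in replicate 2 held at least 5000 axoneme CPM, with medians of 7823 and 6834 CPM. The medians were 1090 and 911 CPM in progenitors I and 16360 and 15598 CPM in MCCs.

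Among microglia of replicate 1, 49 of 289 cells (17.0%, exact 95% interval 12.8 to 21.8) held at least 5000 axoneme CPM, a signal in cells that carry no motile cilia. Free RNA from other cells would give other types a like share, yet 0 of 81 neuroblasts and 0 of 64 oligodendrocytes of that library reached this level, which allows up to 4.45% and 5.6%, so it argues against free RNA as the only cause, though 7 of 68 OPCs (10.3%, 4.24 to 20.1) reached it too. Doublets with lineage cells remain a candidate explanation in replicate 1, where these microglia had 1.98 times the median UMIs of microglia under 500 axoneme CPM (23644 and 11955) and 33.6% of their C1q level. In replicate 2 the 4 such cells of 43 had 43.5% of the C1q level, as doublets would, but 0.180 times the UMIs, which points the other way, and 4 cells are too few to tell. Uptake of lineage cells by microglia was not tested, and neither was any other biological explanation.

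Xist, which no comparison between populations uses, had 269 CPM in replicate 2 against 0.271 CPM in replicate 1. Within replicate 2 it had 313.7 CPM in non-cycling progenitors and 118.7 CPM in early MCCs and MCCs together, without a steady fall between them (349 CPM in early, 195 in mid and 153 in late deuterosomal cells, 97.1 in early MCCs and 133 in MCCs). A smaller share of female cells is a candidate explanation, since cells with Y-linked UMIs alone went from 30.8% to 38.2% in replicate 2 and from 46.3% to 48.3% in replicate 1, a ratio of 1.19 between the libraries (interval 1.03 to 1.38). That interval covers counting error only. With 1 library on each side, the ratio cannot be told apart from any other difference between the cultures. Less Xist per cell is a candidate as well, since cells with Xist and no Y-linked UMIs held 470.3 CPM late in the lineage and 743.9 CPM in progenitors, or 63.2% (91 and 771 cells). The tests leave both open, they may act together, and no biological explanation was tested.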

How the results depend on the processing

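Leaving out unannotated cells or Tubb4b was chosen after the data were seen, and the other settings were planned. Of 2655 values of named genes under settings with a test, 2479 kept their direction and their side of the test, 155 no longer passed, 7 newly passed and 14 changed direction. With 1 replicate left out no fit was rerun, and the 596 values are differences of log2 CPM with 2 counts added. Of these, 440 lay within the root of 2 times the standard error of the full fit. A further 154 lay outside it, and 2 that had passed the test changed direction. Such moves can also come from the other way of estimating. Cdc6 against cycling progenitors was at −6.96 in the fit, but at −5.70 and −5.48 in replicates 1 and 2 alone. Changes of direction in genes that had not passed were not counted as such here. An example is Ccna1 in the deuterosomal stages, at −0.08 in replicate 2 alone. Without unannotated cells the counts were 4212 higher and 5152 lower against cycling progenitors, 5354 and 5659 against non-cycling progenitors, and 3773 and 4944 for the deuterosomal stages. Without the replicate block, which follows the library, they were 3752 and 3539, 4686 and 4434, and 3078 and 3243, and 7, 8 and 19 named genes no longer passed. Gene set tests were not run without the block. With 34 cells per population and library, 10526 genes passed the filter and fewer were called, 1871 higher and 1926 lower, 2144 and 1881, and 1429 and 1531. It ended the most named calls, 16, 26 and 28, of which 4, 10 and 7 had no UMI in some population compared. That setting changed the direction of Gad2 (1.20) and Gmnc (−0.13) against cycling progenitors, Atf3 (0.36), Ccne1 (−0.75), Ccne2 (0.30) and Dlx2 (−0.80) against non-cycling progenitors, and E2f3 (0.94), Mbp (−0.60) and Prim1 (0.66) in the deuterosomal stages, and the cause was not tested. Ccnd3, near 0 in the deuterosomal comparison, was at −0.081 with DESeq2 size factors, −0.15 in thinned cells, −0.076 without the deepest cells and −0.073 with the DESeq2 Wald test. Ccne1 was at −1.09e-04 against non-cycling progenitors without the deepest cells. With 1 replicate left out there is no test, and Ttr ranged from −5.85 to 0.14 and Vtn from −4.65 to 0.17 against cycling progenitors, with the lower value in replicate 2 alone. The share of mid deuterosomal cells was 6.91% without the deepest cells, as mid deuterosomal cells are common among the deepest. In thinned cells the mid deuterosomal level of G2 and M phase genes was 87.0% of cycling progenitors (62.0% without Tubb4b), and S phase genes were at 29.0% in early and 20.7% in mid deuterosomal cells. In cells that were not thinned, 82.9% became 59.7% without Tubb4b. As shares of thinned cells with a UMI the values were 82.2% without Tubb4b, 39.6% and 30.5%. A share weights abundant genes less than a mean CPM does, and whether this accounts for the higher values was not tested. Within progenitors I, which hold fewer cells, 141 and 154 genes differed at least 2-fold between libraries. Between the replicates the lineage ranged from 30.7% to 39.0%, mid deuterosomal cells from 7.32% to 8.07%, MCCs from 6.04% to 17.0%, cycling progenitors from 4.32% to 5.47% and non-cycling progenitors from 34.4% to 44.9%. The list levels ranged from 81.4% to 84.5% for G2 and M phase, 59.5% to 59.9% without Tubb4b, 27.7% to 28.3% for S phase in early and 19.5% to 20.4% in mid deuterosomal cells. Other bin numbers were not run because bins of pseudotime were not used here, and a minimum of 2000 UMIs removed 0 cells.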

Other observations

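The comparisons between single populations in this part and all of its tests were chosen after the data were seen. The 2 non-cycling progenitor populations differed in genes of the lineage. By edgeR, 706 genes were higher and 433 lower in progenitors II than in progenitors I. Gmnc was higher in progenitors II (1.14 ± 0.13 (SE, n = 2 libraries), adjusted p = 1.1e-05), as were Deup1 (1.55 ± 0.22, adjusted p = 0.00038), E2f7 (1.20 ± 0.20), Trp73 (1.24 ± 0.33) and Myb (1.24 ± 0.26). Mcidas (1.13 ± 0.52, adjusted p = 0.229), Ccno (0.66 ± 0.32, adjusted p = 0.273) and Foxj1 (0.73 ± 0.42, adjusted p = 0.380) did not pass the test. Id3 (−1.91 ± 0.28), Id1 (−1.47 ± 0.21), Hes5 (−1.43 ± 0.33), Olig1 (−1.40 ± 0.29) and Olig2 (−1.47 ± 0.30) were lower. Of 40 axoneme genes 26 were higher and 0 lower (camera adjusted p = 1.47e-16, and adjusted p = 0.264 with an estimated correlation). Of 43 S phase genes 2 were higher, and of 54 G2 and M phase genes 2.

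Cell cycle genes were also high in other cell types of the cultures. As a percent of cycling progenitors, S phase genes were at 98.6% ± 6.86 and G2 and M phase genes without Tubb4b at 97.4% ± 7.07 in neuroblasts (SD, n = 2 libraries). The libraries differed more in other types, so their means say little. In replicate 1 and replicate 2 OPCs were at 78.5% and 123.5% for S phase and 68.6% and 105.6% for G2 and M phase, microglia at 28.5% and 51.1%, and 27.7% and 34.4%, and fibroblasts (18 and 22 cells) at 38.4% and 23.0%, and 58.7% and 8.53%. Oligodendrocytes were at 16.5% ± 0.515 and 12.9% ± 0.936. Mid deuterosomal cells were at 19.9% and 59.7%, and the difference in balance between the 2 lists was not tested.

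Mid deuterosomal cells held G2 and M phase transcripts at 59.7% of cycling progenitors. Doublets with cycling progenitors would bring all abundant members in 1 proportion, but over 39 members the excess over non-cycling progenitors, as a share of that in cycling progenitors of class S/G2 or G2/M, ran from 7.84% at the 10th percentile to 72.0% at the 90th in replicate 1. The ratio of these percentiles was 9.19, and 10.4 in replicate 2, with Mki67 at 2.45% and Ckap2l at 158% in replicate 1, which argues against doublets as the whole cause. Free RNA would give all populations a like level, but MCCs held 20.5% of the mid deuterosomal level in replicate 1 and 19.7% in replicate 2. Whether mid deuterosomal cells make these transcripts themselves was not tested, and how the cells were named stays open.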
